A study of Mus musculus with 8 samples.

How the data were processed

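Poly(A)-selected RNA from the livers of male mice was sequenced. The mice were 6 to 8 weeks old when they were put on the GAN diet, which took 40% of its energy from fat and 20% from fructose and held 2% cholesterol, and stayed on it for 26 weeks. Per the labels, RNA integrity numbers lay between 8 and 10, libraries were made with a kit that keeps the strand, and were sequenced as pairs of 150 bases. The submitters' processing notes name STAR 2.7.0f, featureCounts 1.6.3, DESeq2 1.24.0 and the builds GRCm38 and mm10, without the role of each. The authors deposited 1 table of raw read counts per Ensembl gene, with a column for each of the 8 libraries and no normalization. The strand setting of the counting, the annotation release and any filter are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, can be counted for the wrong gene. The total counts set the depth, from 15828526 to 22305064 per library.

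Groups were taken from the genotype label, 4 KO and 4 WT. The titles also carry C and M codes whose meaning is not given, and 2 of the C codes hold both genotypes. Replicate numbers follow accession order and only name the libraries. Gene symbols matched 55450 of 55536 identifiers, and coordinates are those of the GENCODE annotation of GRCm38. The 8 columns were checked for a library deposited more than once. Over genes with a mean count of at least 20, the chi-square per degree of freedom between libraries of a group was at least 12.2, where sampling noise alone gives about 1.

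The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, TMM normalization, filterByExpr by genotype), KO minus WT, two-sided, with Benjamini-Hochberg adjustment over 14899 tested genes and a threshold of 0.05. CPM values are read counts scaled to a common depth with TMM library sizes, and log2 CPM a prior count of 2. TMM factors were 0.948 on average in KO-labelled and 1.06 in WT-labelled libraries (exact permutation p = 0.0286). Each SE was derived from the fitted log2 fold change and its F statistic. The biological coefficient of variation was 0.207. Exact permutation tests of single values were two-sided.

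Lists of genes for pathways, cell types and technical checks were fixed before the data were examined, 43 in all, and 40 had at least 5 tested members. They were tested with camera of limma 3.58.1 with its preset correlation of 0.01, beside camera with the correlation estimated and fry, each adjusted over the lists. A list score is the mean log2 CPM of its tested members in a library.

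The rule for named genes was fixed at the same time. It took Ephb2, the 12 largest changes in each direction among genes past the threshold whose groups did not overlap and whose mean reached 1 CPM in the higher group, up to 4 members past the threshold or else 2 members of each list, the genes past the threshold near Ephb2, and 8 textbook markers. Predicted genes, genes known only by a RIKEN or Ensembl identifier, and further genes of the named set are summarised by count.

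The tests were checked on simulated counts for this comparison, drawn from the means, dispersions and library sizes of the 8 libraries, with 200 changed genes. Of 14688 genes tested, 70% of 100 genes changed by 1 on the log2 scale and 97% of 100 genes changed by 2 were recovered, with 8 false calls among 175. With no gene changed there were 0 calls. A shifted list was recovered and 0 of 39 other lists were called. The simulated genes were drawn independently and these lists were random. The estimated correlation in the real data was 0.42 for the matrix list and 0.85 for the cell cycle list. The simulation therefore does not check the false calls of camera among correlated genes.

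Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter or a stricter filter (1 CPM in 4 libraries), a fit without robust dispersion, a 2-fold limit, the C code as a term, only the C codes that hold both genotypes, and each library left out in turn. Camera was run with the C code as a term too, and list medians were also taken after a loess trend of fold change on GC content and transcript length over all tested genes had been removed. Leaving out KO-labelled replicates 1 and 4 together was added after the principal components had been seen, and so were 3 further settings for Ephb2. Figures were drawn with matplotlib 3.10.9. No gene was left out other than by the filters.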

Results

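RNA was sequenced from livers of male mice labelled as wild type (WT) or knockout (KO) for Ephb2, the gene of a receptor tyrosine kinase that binds membrane-bound ephrin-B ligands on neighbouring cells. Every mouse had been fed a diet high in fat, fructose and cholesterol for 26 weeks, a feeding scheme used to produce steatohepatitis and liver fibrosis. The series held 8 libraries, 4 labelled KO and 4 labelled WT, and genotype was the only condition by which the labels define the groups. The titles also carry C and M codes of unstated meaning that are not spread evenly over the groups. The total counts were 17463870, 19689402, 22305064 and 17368948 reads in KO-labelled replicates 1 to 4 and 18411720, 15828526, 19486739 and 17777807 reads in WT-labelled replicates 1 to 4. The comparison addressed which liver transcripts differed with the Ephb2 genotype on this diet, with fibrosis as the outcome that the series names. The labels do not say outright that each library came from its own mouse, so p-values of tests between libraries measure the spread between these samples. Camera with its preset correlation and Fisher's exact test compare a set of genes with other genes. Their p-values do not measure the spread between samples.

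Ephb2 itself was not lower in the KO-labelled libraries. Ephb2 (ENSMUSG00000028664) lies on the minus strand of chromosome 4 from 136647539 to 136835988 in GRCm38. Its raw counts were 96, 284, 298 and 405 in KO-labelled replicates 1 to 4 and 99, 48, 101 and 317 in WT-labelled replicates 1 to 4. In depth-scaled read counts (CPM), Ephb2 expression was 14.8 ± 7.27 CPM (SD, n = 4) in the KO-labelled group and 7.44 ± 6.29 CPM (SD, n = 4) in the WT-labelled group. The log2 fold change of Ephb2 was 0.99 with a standard error of 0.58, and the edgeR quasi-likelihood test gave an adjusted p of 0.318. Without WT-labelled replicate 4 the log2 fold change was 1.77, and over all settings it ran from 0.66 to 2.12. With sample quality weights in limma-voom, a setting added for Ephb2 after seeing the data, Ephb2 passed as higher in the KO-labelled libraries (log2 fold change 1.45, adjusted p 0.0484). The labels do not state which part of Ephb2 was deleted, and a count over the whole gene can hold reads from exons that a deletion leaves in place. These counts alone neither bear out nor exclude the genotype labels, and the groups are called KO-labelled and WT-labelled throughout. Every direction given below is drawn between libraries so labelled.

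The first principal component held 51.8% of the variance of log2 CPM over 14899 genes and the second held 14.7%. KO-labelled replicate 1 lay at -3.06 on the first component, between the other KO-labelled libraries (24.1 to 62.5) and the WT-labelled libraries (-48.1 to -20.2). Its closest partner was WT-labelled replicate 3, with a correlation of 0.984 across genes, which are not independent replicates. KO-labelled replicate 4 lay apart on the second component, at 51.0.

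**Figure D1:**
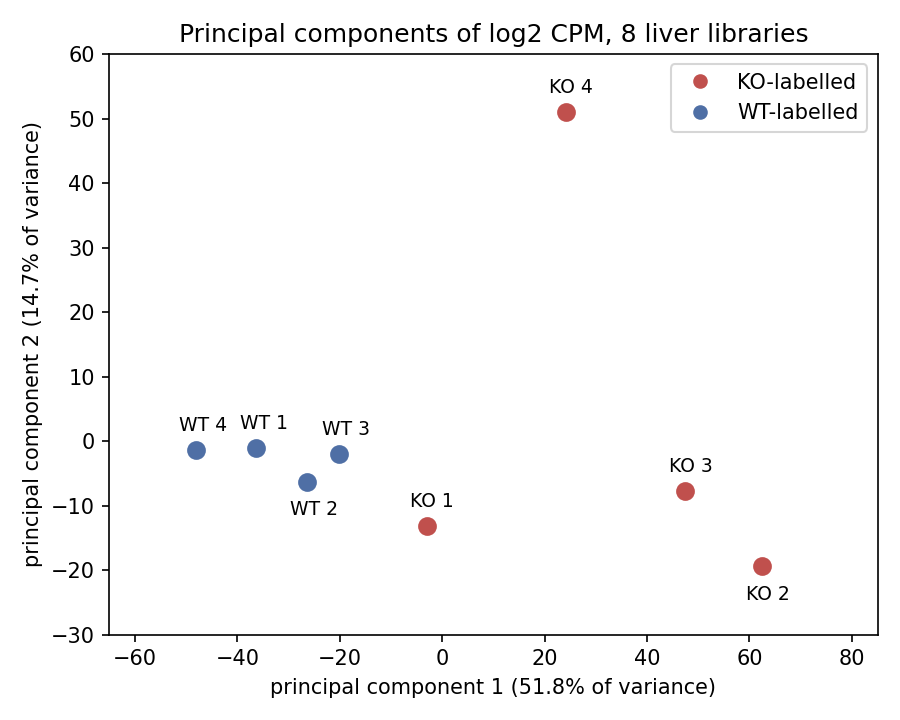
Principal components 1 and 2 of log2 CPM in the 8 liver libraries, with each axis in component units and its percentage of the variance; each point is 1 library, red for KO-labelled and blue for WT-labelled. KO 1 lies at -3.06 on the horizontal axis, next to the WT-labelled libraries, and KO 4 lies at 51.0 on the vertical axis.

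In the KO-labelled livers 18 of 39 extracellular matrix genes, 8 of 21 matrix proteases and inhibitors and 7 of 20 markers of lipid-associated macrophages were lower, with 1 protease higher. In the same livers 7 of 19 major urinary protein genes and 6 of 35 genes of endoplasmic reticulum stress were higher. None of the lists fixed for these groups passed with an estimated correlation (smallest adjusted p 0.183, camera). Col1a1, which encodes a chain of fibrillar type I collagen, fell by 2.45 on the log2 scale, from 41.5 ± 17.1 CPM to 7.59 ± 2.66 CPM (SD, n = 4 each). Gpnmb, a glycoprotein of lipid-laden macrophages, fell by 3.97 on the log2 scale, from 31.8 ± 15.9 to 2.05 ± 1.76 CPM (SD, n = 4 each). Mup3, a major urinary protein secreted by hepatocytes, rose by 2.09 on the log2 scale, from 1138 ± 492 to 4857 ± 1676 CPM (SD, n = 4 each). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 467 ± 91.3 to 830 ± 138 CPM (SD, n = 4 each), a log2 fold change of 0.83.

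Adamtsl2, a secreted matrix-associated protein chosen after its values were seen, had the smallest adjusted p (0.0243, edgeR test) and fell from 20.5 ± 2.58 to 6.92 ± 1.22 CPM (SD, n = 4 each). Of 14899 genes tested with the edgeR quasi-likelihood test, 469 passed a Benjamini-Hochberg adjusted p of 0.05, 125 higher and 344 lower in the KO-labelled livers. At least a 2-fold change was fitted for 262 of them, 25 higher and 237 lower. The 12 largest falls among genes whose groups did not overlap ran from -3.98 (Mmp13) to -3.12 (Mmp12) on the log2 scale and took in H2-Q1 and H2-M2, MHC class I genes with close copies that can share reads, and Ubd, a ubiquitin-like protein. The place of Mmp13 as the largest fall rested on single libraries. Without WT-labelled replicate 4 its log2 fold change was -3.03 and that of Gpnmb -3.61. Without KO-labelled replicate 1 Gpnmb was at -4.71, a larger fall than that of Mmp13 in any setting (-4.31 at the lowest). Leaving out 1 library moved the fitted fold of 16 of 116 named genes by more than 1.5 times, in either direction. Among them, Atp6v0d2 was at -2.55 without WT-labelled replicate 4 on the log2 scale. Mmp12 was at -4.00 without KO-labelled replicate 1, and Bhlha15 was at 4.01 without WT-labelled replicate 1. The 12 largest rises ran from 1.89 (Mup12) to 4.62 (Mup11). The CPM of the groups did not overlap for 468 of the 469 genes, and for 15.4% of all tested genes against the 2.86% that chance gives. The call of single genes depended on single libraries. No gene passed the edgeR test without KO-labelled replicate 2 or without any of WT-labelled replicates 1, 2, 3 or 4, although between 2923 and 3536 genes then had an unadjusted p under 0.05. Only Adamtsl2 passed without KO-labelled replicate 3, whereas 1800 genes passed without KO-labelled replicate 1 and 645 (258 higher, 387 lower) without KO-labelled replicate 4. Over all 8 libraries DESeq2 gave 1873 genes and limma-voom 923. With the C code of the titles as a term, a code of unstated meaning that is the nearest thing to a batch, no gene passed the edgeR test and 2282 had an unadjusted p under 0.05, and within only the C codes that hold both genotypes 46 genes passed, 19 of them among the 469. In both fits only the C codes with both genotypes informed the genotype contrast. KO-labelled replicates 1 and 2 and WT-labelled replicate 4 did not enter it. The C code as a term changed the folds of the 469 genes little: 456 stayed within 1.5 times, and the median size of the log2 fold change went from 1.11 to 1.07. All kept their direction, which the lack of overlap between the groups had nearly fixed. The 469 genes were chosen in these same libraries, so their similar folds are no independent test either. The median standard error rose from 0.207 to 0.275 and the residual degrees of freedom fell from 6 to 3.

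**Figure D2:**
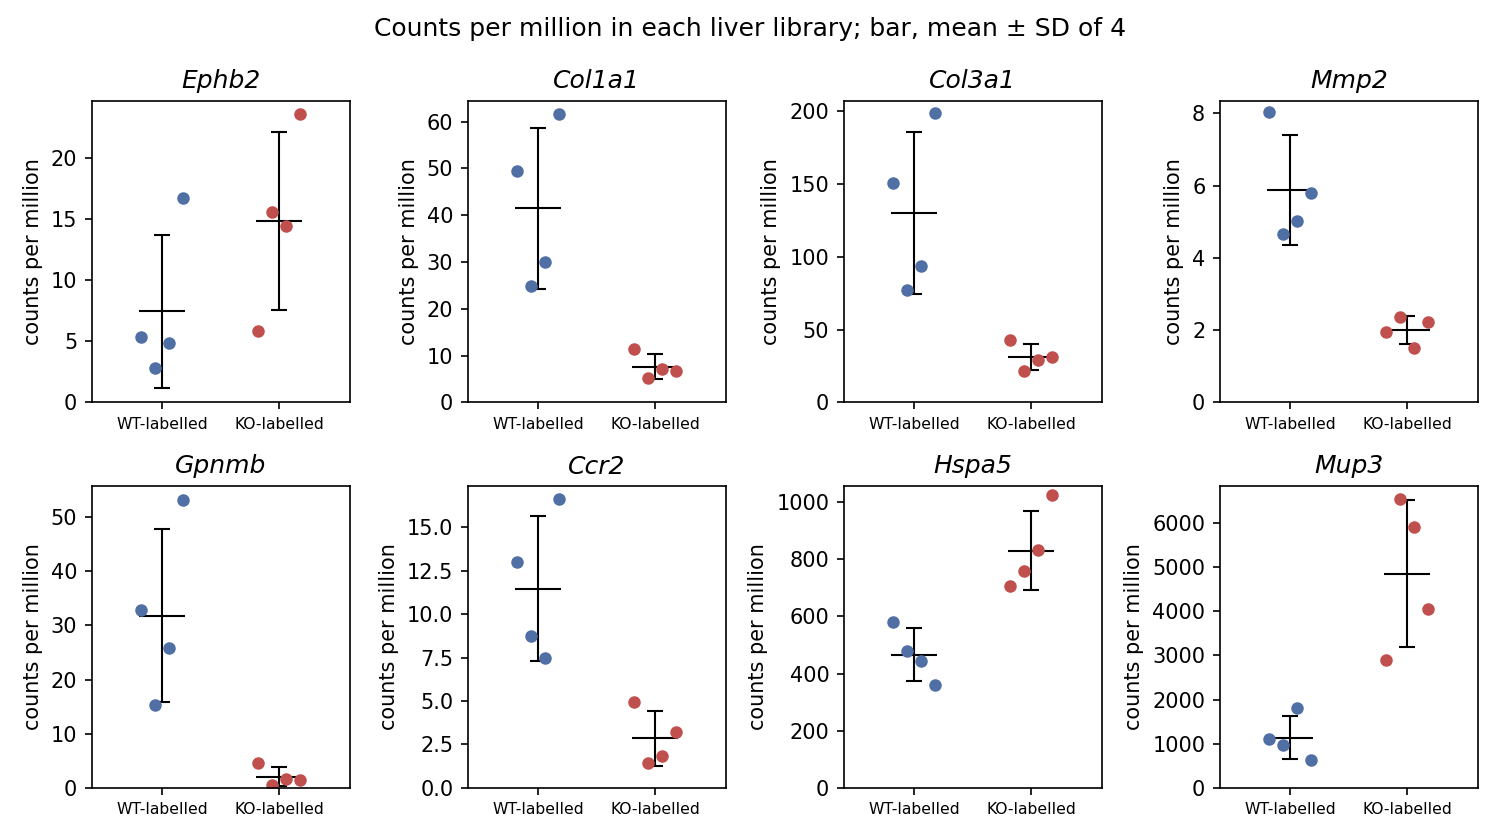
Expression of 8 genes in CPM (vertical axes, from 0) in WT-labelled and KO-labelled livers; each point is 1 library and the bars are the mean ± SD of 4. Ephb2 was not lower in the KO-labelled libraries, and the groups did not overlap for the other 7 genes.

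Genes of the extracellular matrix formed the list with the smallest camera p. Of 39 tested genes on the list of extracellular matrix and collagens, 18 fell, none rose and 21 did not pass (30 lower and 2 higher when adjusted over the list alone). The median log2 fold change of the list was -1.08. Camera with its preset correlation gave an adjusted p of 1.08e-23 for it, and the adjusted p was 0.183 with an estimated correlation. Col3a1, the type III fibrillar collagen, fell from 130.0 ± 55.5 to 31.3 ± 8.96 CPM (SD, n = 4 each), a log2 fold change of -2.06 with a standard error of 0.33. Loxl1, a lysyl oxidase that cross-links matrix fibres, fell by 2.11 on the log2 scale with a standard error of 0.26. Col6a3, a chain of type VI collagen, fell by 1.81 and Thbs2, a matricellular thrombospondin, fell by 1.48 on the log2 scale.

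On the list of matrix proteases and their inhibitors 8 of 21 tested genes fell, 1 rose and 12 did not pass (15 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -1.28. Camera gave an adjusted p of 6.96e-12, and the adjusted p was 0.183 with an estimated correlation. Mmp2, the gelatinase A gene, fell from 5.88 ± 1.51 to 2.00 ± 0.378 CPM (SD, n = 4 each). Timp2, an inhibitor of these proteases, fell by 0.97 and Adamts2, which trims procollagen ends, fell by 1.38 on the log2 scale. The member that rose was Mmp19, with a log2 fold change of 0.32 (chosen after its values were seen). Mmp13, Timp1 and Mmp7 also fell but rested on few reads. Mmp13 had 9 counts over the 4 KO-labelled libraries and 155 over the 4 WT-labelled ones, a depth-corrected ratio of 16.6 with a 95% interval of 8.52 to 37.0 that covers counting error only. WT-labelled replicate 4 had 5.01 CPM of Mmp13 against 0.640 to 1.30 in the others of its group, and without it the fitted log2 fold change of Mmp13 moved from -3.98 to -3.03, and with the C code as a term it was -2.55.

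Stellate cells are the fibroblast-like cells of the liver. Of 19 tested markers of activated stellate cells and myofibroblasts, 3 fell and 16 did not pass (10 lower when adjusted over the list alone). The median of that list was -0.61, with a camera adjusted p of 9.28e-08 and an adjusted p of 0.183 with an estimated correlation. Mfge8, a secreted bridging protein, fell by 1.19 and Vim, the intermediate filament vimentin, fell by 1.18 on the log2 scale, and Pdgfrb, a receptor for platelet-derived growth factor, fell from 17.5 ± 4.49 to 8.72 ± 0.694 CPM (SD, n = 4 each). Acta2, the smooth muscle actin used as a myofibroblast marker, was 2.24 ± 0.583 and 3.01 ± 1.03 CPM (SD, n = 4 each) in KO-labelled and WT-labelled livers, and its adjusted p was 0.408 in the edgeR test. Among 18 markers of quiescent stellate cells, 2 fell (log2 fold changes of -0.91 for Reln and -0.78 for Nrxn1; 8 lower when adjusted over the list alone). That list had a median of -0.50, a camera adjusted p of 4.28e-05 and an adjusted p of 0.365 with an estimated correlation.

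On the list of TGF-beta signalling, a pathway that drives matrix production, 4 of 26 tested genes fell and 22 did not pass (9 lower and 1 higher when adjusted over the list alone). Tgfb3, a ligand, fell by 1.25, Tgfbr2, a receptor, fell by 0.61, and the latent TGF-beta binding proteins Ltbp1 and Ltbp3 had log2 fold changes of -1.21 and -1.54. The median was -0.25, the camera adjusted p was 0.00188, and the adjusted p was 0.183 with an estimated correlation. With the C code as a term this list did not pass camera (median -0.19, adjusted p 0.0685), its median was -0.40 without KO-labelled replicate 4, and it was -0.10 once a trend with GC content and transcript length was taken out. Tgfb1 had a log2 fold change of -0.88 and did not pass (adjusted p = 0.0698, edgeR test). Of 23 YAP and Notch targets 1 fell, Ajuba, with a log2 fold change of -0.97 (6 lower and 1 higher when adjusted over the list alone), with a median of -0.37, a camera adjusted p of 0.00791 and an adjusted p of 0.183 with an estimated correlation. Its median was -0.13 without WT-labelled replicate 4 and -0.22 once the trend with GC content and length was taken out. None of 11 tested Eph receptors and ephrins other than Ephb2 passed (2 lower and 1 higher when adjusted over the list alone). Efna1 had a log2 fold change of 1.15 and Epha7 of -0.85, and the camera adjusted p of the family was 0.435.

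Markers of macrophages that take up lipid were among the genes with the largest differences. Of 20 tested markers of lipid-associated macrophages, 7 fell and 13 did not pass (15 lower when adjusted over the list alone), with a median of -1.52. The camera adjusted p was 2.57e-14, and the adjusted p was 0.183 with an estimated correlation. Trem2, a lipid-sensing receptor of these cells, fell from 6.47 ± 3.05 to 0.981 ± 0.715 CPM (SD, n = 4 each). Atp6v0d2, a subunit of the lysosomal proton pump, fell by 3.33, Mmp12, macrophage elastase, fell by 3.12 and Ctsd, the lysosomal protease cathepsin D, fell by 0.60 on the log2 scale. Spp1, which encodes osteopontin, was 42.5 ± 21.7 CPM in KO-labelled and 124 ± 48.3 CPM in WT-labelled livers (SD, n = 4 each), and its adjusted p was 0.0633 in the edgeR test.

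Other myeloid lists shifted in the same direction. Of 17 markers of monocytes and monocyte-derived macrophages 1 fell, Ccr2, the receptor through which monocytes follow Ccl2, from 11.5 ± 4.18 to 2.86 ± 1.59 CPM (SD, n = 4 each; 9 of the list lower when adjusted over the list alone). The median of this list was -1.27 (-1.95 without KO-labelled replicate 1), with a camera adjusted p of 3.21e-10 and an adjusted p of 0.289 with an estimated correlation. Of 13 dendritic cell markers 3 fell (12 lower when adjusted over the list alone), with log2 fold changes of -1.63 for Cd83, a maturation marker, and of -2.21 and -2.13 for the MHC class II genes H2-Eb1 and H2-Aa. The median was -1.43, with a camera adjusted p of 3.45e-11 and an adjusted p of 0.183 with an estimated correlation. None of 17 markers of Kupffer cells, the resident macrophages, passed (1 lower when adjusted over the list alone). Their median was -0.71, with a camera adjusted p of 0.000169 and an adjusted p of 0.381 with an estimated correlation, and Clec4f was 48.4 ± 24.1 CPM in KO-labelled and 111 ± 33.3 CPM in WT-labelled livers (SD, n = 4 each).

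Of 37 interferon response genes 2 fell, with log2 fold changes of -1.74 for Gbp2 and -0.89 for Ifit3 (17 lower and 1 higher when adjusted over the list alone). The median was -0.54, with a camera adjusted p of 1.02e-08 and an adjusted p of 0.289 with an estimated correlation. None of 26 chemokines and cytokines passed (3 lower when adjusted over the list alone), and Cxcl14 and Ccl5 had log2 fold changes of -2.26 and -2.21. That list had a median of -0.65 (-1.04 without KO-labelled replicate 1), a camera adjusted p of 0.000163 and an adjusted p of 0.365 with an estimated correlation. Ccl2 was 1.02 ± 0.902 CPM in KO-labelled and 1.61 ± 0.820 CPM in WT-labelled livers (SD, n = 4 each). None of 9 T and NK cell markers passed over all genes or when adjusted over the list alone (median -0.91, camera adjusted p 0.00895, and adjusted p = 0.427 with an estimated correlation), and Icos and Cd2 had log2 fold changes of -0.89 and -1.65. This list did not pass camera without WT-labelled replicate 3 (median -0.66, adjusted p 0.136) or with the C code as a term (median -0.81, adjusted p 0.0541).

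Of 35 cell cycle genes 1 fell, Mcm3, a subunit of the replicative helicase, with a log2 fold change of -1.62 (11 lower when adjusted over the list alone). All 35 had a fitted log2 fold change below 0, with a median of -1.58, which was -2.39 without KO-labelled replicate 1 and -0.99 without WT-labelled replicate 1. The camera adjusted p was 2.20e-12, and the adjusted p was 0.377 with an estimated correlation. Of 17 markers of cholangiocytes, the epithelial cells of bile ducts, 2 fell, Krt7, a keratin, from 1.83 ± 0.467 to 0.604 ± 0.166 CPM, and Bicc1 from 16.7 ± 4.24 to 6.82 ± 1.61 CPM (SD, n = 4 each; 8 lower when adjusted over the list alone). Their median was -1.14, with a camera adjusted p of 1.22e-05 and an adjusted p of 0.289 with an estimated correlation. None of 20 oncofetal and tumour-associated genes passed (4 lower when adjusted over the list alone; Scd2 -1.18 and Golm1 -0.94 on the log2 scale), with a median of -0.92, a camera adjusted p of 2.30e-06 and an adjusted p of 0.183 with an estimated correlation. Of 23 liver endothelial markers 1 fell, Cd34, with a log2 fold change of -1.73 (1 lower when adjusted over the list alone), and the median was -0.21, with a camera adjusted p of 0.00115 and an adjusted p of 0.598 with an estimated correlation. The endothelial median was -0.32 without WT-labelled replicate 2, -0.13 without WT-labelled replicate 4 and -0.089 once the trend with GC content and length was taken out, and the list did not pass camera with the C code as a term (median -0.14, adjusted p 0.0707).

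Among genes that were higher in the KO-labelled livers, male-biased liver genes had the highest list median. Of 23 tested genes on that list 4 rose and 19 did not pass (10 higher and 1 lower when adjusted over the list alone), with a median of 0.999. The camera adjusted p was 2.29e-10, and the adjusted p was 0.289 with an estimated correlation. Mup11 rose by 4.62 and Susd4, a complement regulator, by 2.54 on the log2 scale, and Serpina1e, a protease inhibitor of plasma, rose from 822 ± 157 to 1642 ± 133 CPM (SD, n = 4 each). The Mup genes are nearly identical copies, so their reads can be assigned to the wrong member. Of 19 tested Mup genes 7 rose and all 19 had a fitted log2 fold change above 0. Summed over the family, they took 11855 ± 3389 CPM in KO-labelled and 4813 ± 1881 CPM in WT-labelled livers (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow). Of 12 female-biased genes 1 fell, Atp6v0d2, a lysosomal pump subunit that is also on the macrophage list (2 lower when adjusted over the list alone). That list had a median of -1.05, a camera adjusted p of 0.000104 and an adjusted p of 0.281 with an estimated correlation.

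Of 35 genes of endoplasmic reticulum stress and the unfolded protein response 6 rose and 29 did not pass (10 higher when adjusted over the list alone). Syvn1, a ubiquitin ligase that marks misfolded proteins for degradation, rose from 26.8 ± 2.85 to 59.4 ± 12.3 CPM (SD, n = 4 each). Dnajb9, a co-chaperone of Hspa5, rose by 0.79 and Manf, a secreted stress protein, by 0.94 on the log2 scale. The median of the list was 0.41, with a camera adjusted p of 8.44e-10 and an adjusted p of 0.289 with an estimated correlation. Bhlha15, a transcription factor of secretory cells, rose by 3.27 on the log2 scale, from 0.247 ± 0.223 to 2.38 ± 1.11 CPM (SD, n = 4 each).

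Of 25 hepatocyte identity genes 1 rose, Serpina1c, by 1.14 on the log2 scale (1 higher when adjusted over the list alone), with a median of 0.22, a camera adjusted p of 0.00115 and an adjusted p of 0.414 with an estimated correlation. The median of that list was 0.12 without KO-labelled replicate 2, and with the C code as a term it was 0.0038 and the list did not pass camera (adjusted p 0.242). Serpina1c and Serpina1e belong to a family of close copies and can share reads. Of 25 genes of gluconeogenesis and insulin signalling 1 rose, Irs2, an adaptor of the insulin receptor, from 15.8 ± 2.42 to 32.0 ± 5.10 CPM (SD, n = 4 each; 1 higher when adjusted over the list alone). The median was 0.18, with a camera adjusted p of 0.0108 and an adjusted p of 0.394 with an estimated correlation. The list did not pass camera with the C code as a term (median 0.15, adjusted p 0.345), and its median in the fit without that term was 0.32 once the trend with GC content and length was taken out. None of 13 mitochondrially encoded genes passed (8 higher when adjusted over the list alone). Their median was 0.46, with a camera adjusted p of 3.46e-06 and an adjusted p of 0.365 with an estimated correlation, and they took 8.94 ± 1.32% of counts in KO-labelled and 7.48 ± 0.838% in WT-labelled livers (SD, n = 4 each; exact permutation p = 0.114). None of 27 acute phase genes passed over all genes or when adjusted over the list alone. Their median was 0.85 with a camera adjusted p of 0.00791 and an adjusted p of 0.737 with an estimated correlation, and without KO-labelled replicate 4 the direction turned, with a median of -0.08.

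**Figure D3:**
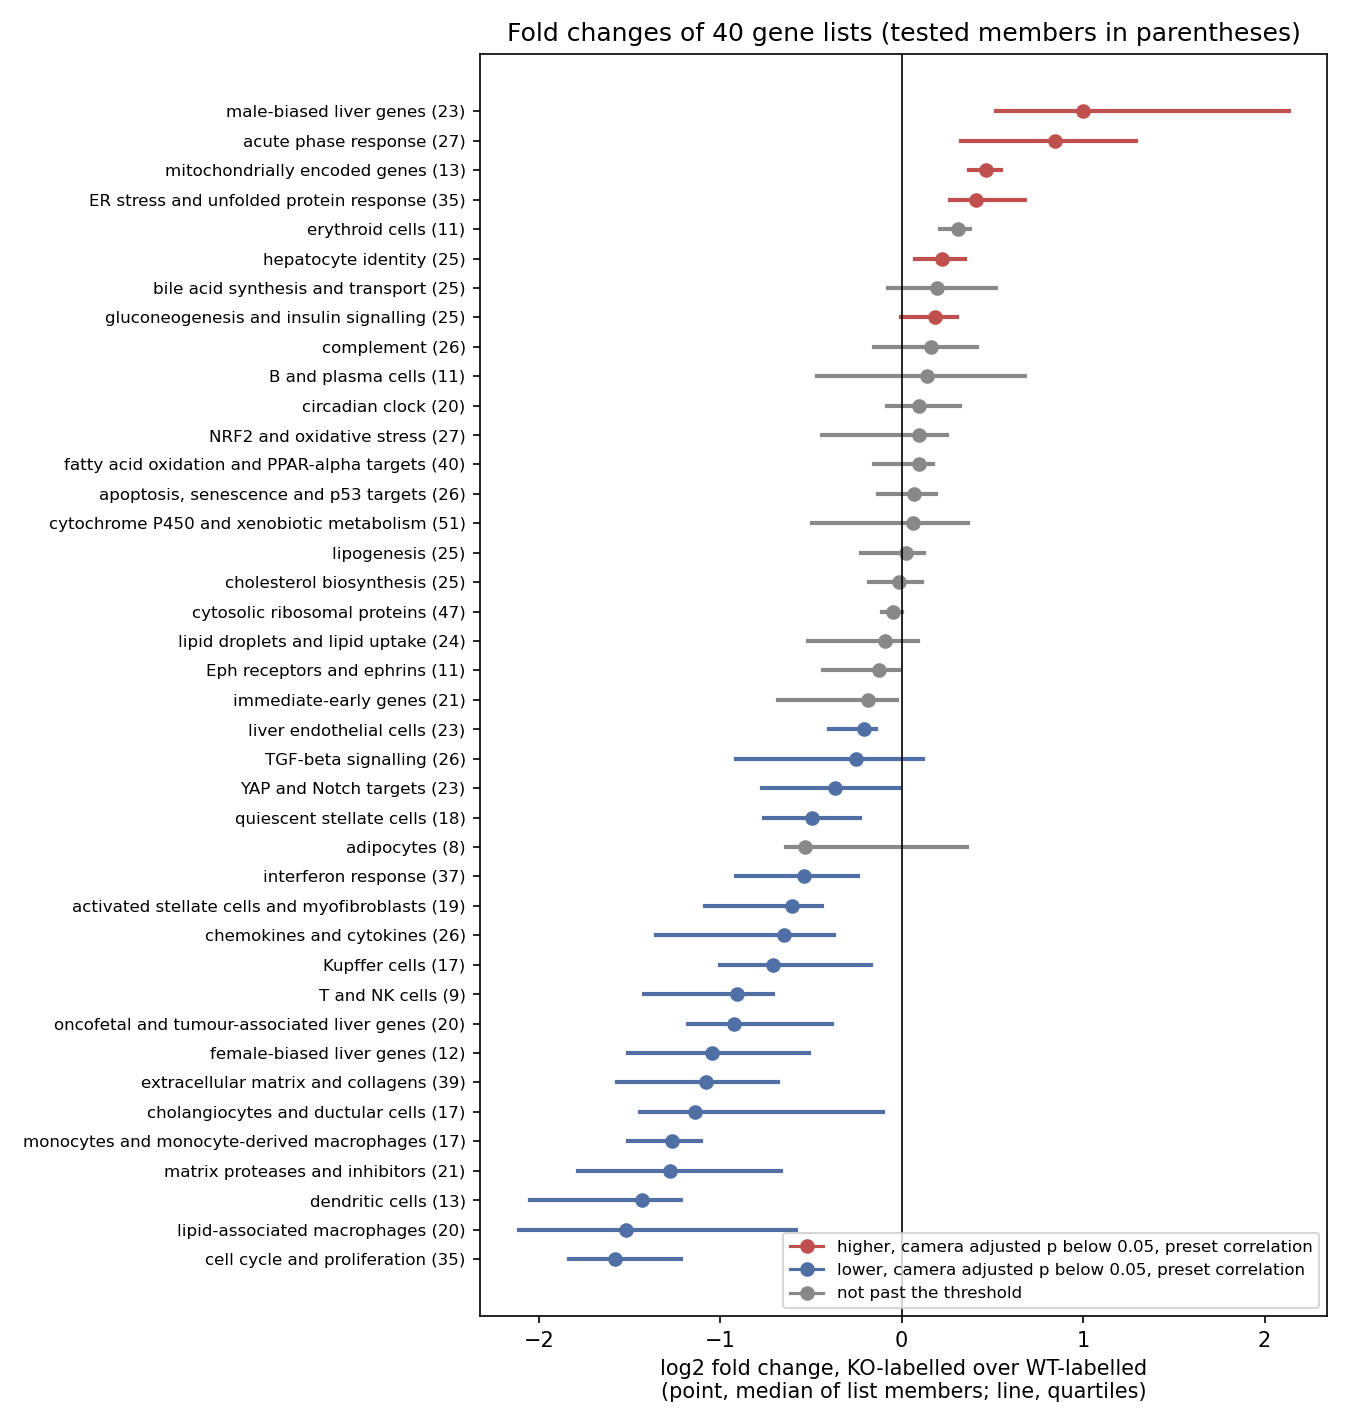
Median (point) and quartiles (line) of the log2 fold change, KO-labelled over WT-labelled, of the tested members of 40 gene lists, with the number of members in parentheses; colour marks lists past a camera adjusted p of 0.05 with the preset correlation. Medians ran from -1.58 for the cell cycle list to 0.999 for male-biased genes, and no list passed with an estimated correlation.

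In all, 24 of 40 tested lists passed camera with the preset correlation, 6 higher and 18 lower. None passed with an estimated correlation, where 8 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move one way on balance, 9 passed. At a fry adjusted p of 0.0196 each were matrix, matrix proteases, lipid-associated macrophages, dendritic cells and activated stellate cells. So were TGF-beta signalling, YAP and Notch targets and oncofetal genes, and cholangiocytes were at 0.0443. Lists past camera that fry did not pass included endoplasmic reticulum stress (0.0526), male-biased genes (0.0770) and cell cycle (0.104). The mixed test of fry, which counts changes in either direction, passed 30 lists. Among them were some that did not pass camera, such as Eph receptors and ephrins and circadian clock (fry mixed adjusted p 0.0030 each). The mean log2 CPM of 11 lists separated the groups at an exact permutation p of 0.0286, with an adjusted p of 0.104.

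The 16 other lists did not pass camera. Lipogenesis (median 0.03, adjusted p 0.975), cholesterol biosynthesis (-0.02, 0.957), fatty acid oxidation and PPAR-alpha targets (0.09, 0.522), lipid droplets and lipid uptake (-0.09, 0.390) and bile acid synthesis and transport (0.19, 0.0734) held no gene that passed over all genes or when adjusted over the list alone. The same held for complement (0.16, 0.561), apoptosis, senescence and p53 targets (0.07, 0.957), B and plasma cells (0.14, 0.975), cytosolic ribosomal proteins (-0.05, 0.561), erythroid cells (0.31, 0.363) and adipocytes (-0.53, 0.363). Of 51 genes of cytochrome P450 and xenobiotic metabolism (0.06, 0.975), 2 rose, Cyp2c29 by 0.71 and Cyp2c54 by 2.02 on the log2 scale (3 higher and 2 lower when adjusted over the list alone), and these close copies can share reads. Of 27 NRF2 and oxidative stress genes (0.10, 0.975) 1 fell, G6pdx, with a log2 fold change of -0.98 (2 lower and 1 higher when adjusted over the list alone). Of 20 circadian clock genes (0.10, 0.152) Clock and Bhlhe41 rose by 0.45 and 1.57 and Wee1 fell by 0.65 on the log2 scale (4 higher and 1 lower when adjusted over the list alone). Of 21 immediate-early genes (-0.19, 0.190) 1 fell, Egr2, which had 9 counts in all KO-labelled and 91 in all WT-labelled libraries (1 lower and 1 higher when adjusted over the list alone). The median and the mean differed in sign for fatty acid oxidation (mean -0.04), complement (-0.08), apoptosis (-0.08), cytochrome P450 (-0.07), B and plasma cells (-0.0046), NRF2 (-0.13) and lipogenesis (-0.02), and camera pointed against the median for apoptosis and lipogenesis. Neutrophil, pancreatic acinar and mesothelial markers had 3, 1 and 3 members with enough reads and were not tested as lists, and none of these members passed. S100a8 and Csf3r (neutrophils) had log2 fold changes of -0.13 and -0.94, Cela1 (acinar cells) of -0.47, and Gpm6a and Muc16 (mesothelial cells) of -1.08 and -0.24.

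Leaving out 1 library brought other lists past camera. Without KO-labelled replicate 4 these were bile acid synthesis (adjusted p 0.000225), circadian clock (0.0128) and, with its direction turned, cholesterol biosynthesis (0.0308). Bile acid synthesis also passed without WT-labelled replicate 3 (0.0473), immediate-early genes without KO-labelled replicate 1 (0.0175) and erythroid cells without KO-labelled replicate 2 (0.0105). With the C code as a term immediate-early genes (adjusted p 0.000121), cholesterol biosynthesis (0.00140), complement (0.00924) and lipogenesis (0.0124) passed camera, and so did cytochrome P450 (0.00254) and B and plasma cells (0.00814) with their direction turned. In that fit the only KO-labelled libraries in the genotype contrast were replicates 3 and 4. KO-labelled replicate 4 had scores of 7.29 for lipogenesis and 4.56 for cholesterol biosynthesis, below the rest of its group.

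Genes next to Ephb2 were compared with the rest, because a targeted allele carries flanking DNA of the strain in which it was made. Of the 100 nearest tested genes, 50 on each side from 133584362 to 141547892 on chromosome 4, 4 passed, against 465 of 14798 other genes. The odds ratio was 1.28 with a 95% interval of 0.342 to 3.42 (Fisher's exact test, two-sided p = 0.559; genes are not independent replicates). Sh3bgrl3, Man1c1, Alpl and Atp13a2 were the 4 genes, with log2 fold changes of -1.16, -1.10, -0.65 and -0.40. With 25 genes on each side the odds ratio turned to 0.627, and with an unadjusted p under 0.05 as the threshold it was 1.64 (Fisher's exact p = 0.0210).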

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

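The tests of the matrix lists, of exchanged labels and of the Mup genes were chosen after the results were seen; the test of the place of KO-labelled replicate 1 was set before its result was seen.

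The first pattern is the lower matrix, protease and lipid-associated macrophage lists in the KO-labelled livers. A scaling error common to a library is argued against by the matrix score minus the ribosomal protein score within each library, which no scaling changes and which differed by -0.979 on the log2 scale (exact permutation p = 0.0286, the smallest possible). A uniform loss of all cells other than hepatocytes is argued against as the whole cause by the matrix, protease and lipid-associated macrophage scores minus the endothelial score, at -0.712, -0.954 and -1.27 (exact permutation p = 0.0286 each). It stays open for Kupffer cells and cholangiocytes, whose scores minus the endothelial score, at -0.377 (exact permutation p = 0.286) and -0.607 (exact permutation p = 0.0571), did not separate the groups. A trend with GC content or transcript length is argued against as the whole cause, since the matrix median moved from -1.08 to -0.971 once that trend was taken out. A difference in stellate cell and macrophage numbers, or in their expression, by Ephb2 genotype or by anything else that differs with the labels, remains a hypothesis that may explain the pattern and cannot be tested further in bulk tissue.

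The second pattern is that Ephb2 was not lower in the KO-labelled libraries, while KO-labelled replicate 1 lay near the WT-labelled ones. An exchange of labels between 1 KO and 1 WT library stays open. The highest of the 16 splits with such an exchange gave 0 genes by the edgeR test against 469 by label (1873 by label with DESeq2, and no other tool was run on the exchanges). Such a count finds the clearest separation, whatever its source. It also fell to 0 when KO-labelled replicate 2 or any WT-labelled library was only left out. The Ephb2 counts crossed the labels, with 96 in KO-labelled replicate 1 and 317 in WT-labelled replicate 4. Reads from parts of Ephb2 that the deletion left in place may explain the lowest KO-labelled count of 96, and this cannot be told apart from an intact gene because a gene count does not place reads along the gene. A wrong label of KO-labelled replicate 1 alone also stays open: on the scale from the WT mean (0) to the mean of the other KO-labelled libraries (1) its median place over leading genes was 0.387, between the limits of 0.25 and 0.5 set for the answer. Placed in the same way, the WT-labelled libraries lay at -0.211 to 0.296 and the other KO-labelled ones at 0.598 to 1.34. The matrix score of KO-labelled replicate 1 lay at 0.697 on the same scale. With its label changed 1495 genes passed the edgeR test, against 469 as labelled and 1800 with it left out. Changing the label of KO-labelled replicate 4 gave 4 genes, and changing that of any other library gave 0. KO-labelled replicate 1 was thus the only library whose changed label raised the count. That count cannot decide whether the label is wrong, because it finds the clearest separation, whatever its source.

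The third pattern is the higher Mup genes in the KO-labelled livers. Reads misassigned among members of the family cannot change its sum, so the sum is no test of them. It shows only that the family total was 2.46 times as high in KO-labelled livers. The exact permutation p of that difference was 0.0286, and 0.0667 when adjusted over the library measures tested. The sum cannot decide the folds of single members, such as 24.6 times for Mup11, which stay open to misassigned reads. A variant of the Mup gene cluster alone stays open and cannot be told apart from a wider shift of male-biased genes. The named Mup genes lie on chromosome 4, as Ephb2 does, from 60658466 (Mup11) to 62087342 (Mup3). That stretch is outside the window of 50 genes on each side of Ephb2. Male-biased genes outside the family had a score difference of 1.16 (exact permutation p = 0.0857), which missed the threshold although 16 of 17 had a fitted log2 fold change above 0. Female-biased genes go the way a wider shift would, with a median log2 fold change of -1.05 and 11 of 12 fitted below 0, but their score also missed the threshold (difference -1.28, exact permutation p = 0.0571). A difference in sex-biased expression by Ephb2 genotype stays open, and hormones were not measured.

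KO-labelled and WT-labelled values were each searched for a library far from its group. Among 328 groups of 4 libraries, 20 held a library far from the other 3, where chance gives about 16.4 (about 1 in 20). KO-labelled replicate 4 had 18.7 CPM of Gtpbp4-ps1, 448 CPM of Crp and 105 CPM of Manf, each above its group, and scores of 8.92 for the acute phase response, above its group, and of 7.29 for lipogenesis and 4.56 for cholesterol biosynthesis, below its group. KO-labelled replicate 1 had 0.726 CPM of Cd2, 3.09 CPM of Cd22 and 16.6 CPM of Ifit3, above its group, and 1120 CPM of Serpina1c, below it. KO-labelled replicate 2 had 130.0 CPM of Dnajb9, above its group. WT-labelled replicate 4 had 2018 CPM summed over the Mup family and 22.5 CPM of Syvn1, below its group, and 5.01 CPM of Mmp13 and 45.4 CPM of Mmp12, above it. The same library had scores of 10.1 for hepatocyte identity, below its group, and of 3.98 for YAP and Notch targets and 5.78 for adipocytes, above it. WT-labelled replicate 3 had 67.0 CPM of Cebpb and WT-labelled replicate 1 had 144 CPM of Rpl41, above their groups.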

How the results depend on the processing

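The fits without KO-labelled replicates 1 and 4 together, and for Ephb2 the sample quality weights, the fit that was not robust and the fit in only the mixed C codes, were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the replicate numbers follow accession order and name no pairs; the C codes, whose meaning is not given, entered as a block, with the counts given here.

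Each of the 469 genes kept its direction in every setting that tested it (447 of them with the stricter filter). The groups did not overlap in CPM for 468 of them, so a kept direction was nearly fixed in advance and is no test. The number past the threshold varied. It was 1873 (581 higher, 1292 lower) by DESeq2, 923 (199 and 724) by limma-voom, 2714 (1018 and 1696) with sample quality weights, 737 (201 and 536) with no low-count filter and 262 (25 higher) with a 2-fold limit. With the C code as a term it was 0 (0 higher, 0 lower) by edgeR, with 2282 genes at an unadjusted p under 0.05, and in only the C codes with both genotypes it was 46 (17 and 29). Leaving out 1 library gave 0 to 1800 genes, 0 to 558 higher and 0 to 1242 lower, and leaving out KO-labelled replicates 1 and 4 gave 2474 (817 and 1657). It stayed within 1.5 times the main count with DESeq2 size factors (440), the stricter filter (462) and a fit that was not robust (546). The cause was not tested.

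Ephb2 passed only with sample quality weights, as higher (log2 fold change 1.45), and was above 0 in all settings run for it, at 0.66 to 2.12. Of the 40 lists, 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05. By fry 9 passed for direction and 30 in the mixed test. With the C code as a term 5 lists that had passed camera did not, and 4 passed that had not, beside those that turned. Leaving out 1 library gave 3 to 15 lists whose scores differed at an exact p under 0.05. The odds ratio near Ephb2 was 0.627 with 25 genes on each side and 1.64 at an unadjusted p. Over the named genes and settings, 536 values lost the threshold, 96 gained it, 1079 kept side and direction and 5 turned. Leaving out 1 library, S100a8 ranged from -0.86 to 0.29 and Muc16 from -0.62 to 0.076 on the log2 scale.

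The direction of the list test turned in 39 of the combinations of list and setting, and list medians are given for these. By fry they were 0.137 (B and plasma cells), 0.0628 (cytochrome P450) and 0.0955 (NRF2). With the stricter filter they were 0.0549 (cytochrome P450) and 0.0881 (NRF2). With the C code as a term they were -0.427 (B and plasma cells), -0.0322 (fatty acid oxidation), -0.0589 (lipid droplets), -0.260 (cytochrome P450), -0.0488 (NRF2) and -0.232 (adipocytes). Without KO-labelled replicates 1 and 4 they were -0.753 (B and plasma cells), 0.0922 (complement), -0.115 (acute phase), 0.137 (lipogenesis), 0.0477 (cholesterol biosynthesis) and 0.000779 (NRF2). Leaving out 1 library, medians ran from -0.593 to 0.372 (B and plasma cells), 0.0375 to 0.243 (complement), -0.0756 to 1.22 (acute phase), -0.0598 to 0.118 (lipogenesis), -0.0908 to 0.112 (cholesterol biosynthesis), 0.0310 to 0.144 (fatty acid oxidation), -0.0883 to 0.133 (cytochrome P450), -0.00832 to 0.145 (NRF2), -0.0205 to 0.0686 (apoptosis), -0.632 to -0.217 (adipocytes) and -0.0995 to 0.0526 (ribosomal proteins). Of these lists only acute phase had passed camera. The cause was not tested.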

Other observations

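The secretory transport and MHC class II lists were chosen after the result was seen; the tests of other splits and of the genes near Ephb2 were set before their results were seen.

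Of 55 tested genes that move proteins through the endoplasmic reticulum and on to the Golgi apparatus, 8 rose, none fell and the rest did not pass, with a median log2 fold change of 0.17 and 52 fitted above 0. Arfgap3, a regulator of vesicle coats, rose from 11.7 ± 1.46 to 21.0 ± 3.54 CPM and Creb3l2, a transcription factor of the secretory pathway, from 25.4 ± 2.97 to 45.4 ± 8.46 CPM (SD, n = 4 each; both chosen after their values were seen). The list was put together after genes of this pathway had been seen to rise in these libraries, so its score, higher by 0.223 log2 CPM, decides nothing and a rise across the pathway stays open.

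Of 10 tested genes of MHC class II antigen presentation 5 fell, H2-Aa, H2-Eb1, H2-DMa, H2-DMb1 and Ciita, and 5 did not pass, while all 10 had a fitted log2 fold change below 0, with a median of -2.04. Ciita, the transcriptional activator of these genes, fell from 13.2 ± 5.01 to 3.23 ± 1.57 CPM (SD, n = 4 each; H2-DMa, H2-DMb1 and Ciita were chosen after their values were seen). The list was put together after H2-Aa and H2-Eb1 had been seen to fall in these libraries, so no test of it is given.

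If the libraries are otherwise exchangeable, the other splits of the 8 libraries argue against chance as the source of the 469 genes. The share of 0.0286 is the smallest that 4 against 4 allows, so it cannot exclude chance. Of 35 splits into 4 and 4, 1 gave as many genes, the split by label, and the highest of the others gave 1 gene. The splits take no account of the C codes, which are unevenly spread over the groups. With the C code as a term 0 genes passed the edgeR test (2282 at an unadjusted p under 0.05), and 46 passed in only the codes with both genotypes. Near Ephb2 the odds ratio of 1.28 leaves an effect of flanking DNA open. The bound written for the absence of enrichment, an interval that includes 1, was too weak, because the interval of 0.342 to 3.42 also holds a large enrichment.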
